A study of Homo sapiens with 24 samples.

How the data were processed

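Expression was measured by RNA sequencing in blood eosinophils, granulocytes of allergic inflammation, from 3 donors with allergy and mild asthma. Cells of each donor were cultured with IL-3, a cytokine that signals through the beta common receptor chain, at 2 ng/ml or without it (resting), for 4 h or 20 h. Per the labels, RNA was isolated on columns with DNase treatment, full-length cDNA was amplified with a low-input SMARTer kit, and libraries were made by tagmentation. Amplified low-input cDNA adds noise to weakly expressed genes, and reads counted after amplification are not independent molecules. The labels list 24 libraries, 2 per donor and group, while the deposited table has 12 columns, 1 per donor and group. Whether a column holds 1 of these libraries or both, and how they were combined, is not stated. Each column was therefore taken as 1 sample and the donor as the replicate (3 columns per group).

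The values are, per the file headers, the log2 of total RPKM (reads per kilobase of gene model, scaled to the reads of the library), computed by the authors. The processing notes name CASAVA and the genome build GRCh38 without versions, and the gene models are RefSeq. The aligner and the counting method are not stated. RPKM was recovered as 2 to the power of the deposited log2 value. All undetected genes share a floor of -9.55687, exactly 1.0 log2 unit under the next lowest value of -8.55687, and the floor was set to 0. The table had 38033 rows. Left out were 28 rows whose symbol had become a calendar date, so that the gene could not be told, and XIST and Y-linked genes in every table. Rows that shared a symbol were summed, which merged 51 rows, and 37820 genes remained.

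No read totals are given, so depth was estimated from the steps between values, because a gene with few reads takes RPKM values in whole multiples of the value of 1 read. Of 19465 genes searched, 5528 (28.4%) held whole multiples of 1 step in every column, within 0.02 reads. The most common steps gave depths of 7.68 to 10.5 M reads per column, with the absolute scale set by 278 of 3804 genes. One read over 1 kb then stands for 0.0956 to 0.130 RPKM, and RPKM 1 over 2 kb for 15.4 to 20.9 reads. The depth estimate returned ratios of 1.0 to the true depth in 12 simulated columns. The simulation drew whole reads for 1 library per column, as the estimate assumes. It cannot check the depths of deposited columns that may combine libraries. These figures cover counting error only.

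Genes with RPKM of at least 1 in at least 3 of the 12 columns were tested, 12383 in all. Their log2(RPKM + 0.5) values were fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend, the 4 groups in 1 fit and donor as a block (6 residual and 3.44 prior degrees of freedom). The pairing by donor was checked on residuals from the group means: columns of the same donor correlated across genes at 0.295 to 0.476 in 18 pairs, and columns of different donors at -0.29 to -0.067. Deviations from a group mean cancel out within the group, so positive values within donors force negative ones on average between donors. The negative values are therefore no separate evidence of the pairing. Genes are not independent replicates. The comparisons were IL-3 against resting at 4 h and at 20 h, 20 h against 4 h in resting cells and with IL-3, and the difference between the IL-3 effects at both times (interaction). Benjamini-Hochberg adjustment ran over all genes tested, and genes with adjusted p under 0.05 were called. Levels are mean RPKM ± SD over the 3 donors, and log2 fold changes are given with the SE from limma. In simulated data with 200 changed genes per comparison, 100 of each size, limma recovered 65% of changes of log2 1 and 84% of log2 2 at 4 h, 56% and 81% at 20 h, and 34% and 79% for the interaction. Unchanged genes made up 3.2% to 6.8% of the simulated calls. The simulation changed far fewer genes than were called in the data and drew noise independently for each gene. These rates therefore need not hold for the data.

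The comparisons, the tests, 30 gene lists and the rule for named genes were fixed before the data were examined. The lists covered IL-6 family signalling, beta common cytokine receptors and STAT5 targets, eosinophil granule and lineage genes, cytokines, activation and adhesion proteins, MHC class II presentation, anti-apoptotic and pro-apoptotic genes, eicosanoids, proteases, ribosomal proteins, ribosome biogenesis, cholesterol, glycolysis, oxidative phosphorylation, interferon-stimulated genes, NF-kappaB feedback, immediate early genes, ER stress, glucocorticoid-responsive genes, cell cycle, mitochondrially encoded genes, and markers of neutrophils, T cells, NK cells, B cells, monocytes, basophils and mast cells, platelets and erythroid cells. Of 727 entries 722 were in the table, 16 of them under another symbol. Lists were tested with camera (preset inter-gene correlation 0.01, with an estimated correlation beside it), which compares a list with all other genes, and with fry, which tests whether a list's genes move one way on balance or change in either direction. Both were adjusted over the 30 lists of a comparison. Lists share genes, so their results are not independent. PIM1, PIM2 and PIM3 are on the beta common and the anti-apoptotic lists, and OSM is on the IL-6 family, beta common and cytokine lists. The named genes are the 10 largest rises and the 10 largest falls for each IL-3 comparison, and 5 and 5 for the others. They had to be called, to move the same way in all 3 donors and to reach a mean of 5 RPKM in the higher group. Up to 4 members with the smallest p were added for each described list, and IL6, IL6R, IL6ST, ADAM10, ADAM17, IL3RA, IL5RA, CSF2RB, CISH and CLC are always given. Immunoglobulin and T cell receptor genes and entries without an approved-style symbol were excluded from naming. The results of 1 gene that the rule named were left out after the analysis, and no other gene took its place. The rule also took rows of small RNAs, 59 to 97 nucleotides long, whose highest group mean rests on 3 to 30.4 estimated reads. The next genes in rank without such rows were therefore added after the values were seen. Because the libraries were made from full-length cDNA, reads on small RNA rows may belong to longer transcripts over the same place. Their source was not tested, so changes of these rows are not taken as changes of the small RNAs. Positions of genes are those of the GRCh38.p14 RefSeq annotation.

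The alternatives were pseudocounts of 0.1 and 1, no filter on low values, a minimum of 5 RPKM, median-ratio scaling, quantile normalization, no donor block, limma without the trend, only the groups compared, a minimum log2 fold change of 1, an estimated inter-gene correlation and leaving out each donor. Added after the data were seen were fits without the IL-3 4 h column of donor 2, without the resting 20 h column of donor 1, and without small RNA rows. Alternatives on the 24 single libraries were not run, because the table has only 1 column per donor and group. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9 were used for the depth estimate and the plots.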

Results

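RNA levels of blood eosinophils from 3 donors were compared in 4 cultures, resting and with IL-3 at 4 h and at 20 h, with 1 column of RPKM values per donor and culture (n = 3 per group). Estimated depth lay between 7.68 and 10.5 M reads per column and overlapped between the groups. Within every donor the IL-3 column was deeper than the resting column at both times. The gap was smallest in donor 2 at 4 h (8.48 M resting, 8.62 M with IL-3) and largest in donor 2 at 20 h (7.76 and 9.92 M). Each column listed 10790 to 11948 genes at RPKM 1 or more. Between 15853 and 22976 genes were listed above 0, and the highest number, in the IL-3 4 h column of donor 2, came at a depth of 8.62 M reads. Eosinophil genes were abundant: CLC, which encodes the Charcot-Leyden crystal protein (chromosome 19, 39731255 to 39738029), had 3240 ± 920 RPKM in resting cells at 4 h and 13900 ± 580 at 20 h (SD, n = 3). CCR3, the eotaxin receptor, had 2190 ± 255 and 1750 ± 274 RPKM in the same cultures. Markers of other blood cells were present and varied between donors, such as CD14 of monocytes at 9.02 ± 13.0 RPKM and CD79A of B cells at 14.9 ± 16.7 RPKM in resting cells at 4 h.

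**Figure D1:**
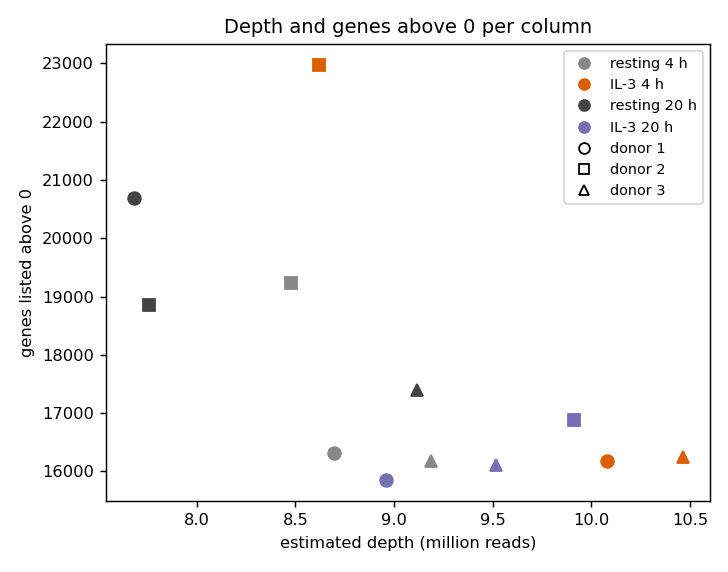
Genes listed above 0 (y axis) against estimated depth in M reads (x axis) for the 12 columns, coloured by culture, with a symbol per donor. The column with 22976 genes is the IL-3 4 h culture of donor 2.

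The title of the series concerns IL-6 trans-signaling, in which IL-6 bound to a soluble form of its receptor acts on cells through the shared chain IL6ST (gp130). IL6R (chromosome 1, 154405343 to 154469450), which encodes the IL-6 receptor alpha chain, was expressed in all 4 cultures. Its level was 72.5 ± 11.9 RPKM in resting cells at 4 h, 54.2 ± 10.2 with IL-3 at 4 h, 46.4 ± 1.91 in resting cells at 20 h and 24 ± 5.33 with IL-3 at 20 h. IL6R fell with IL-3 at 20 h by 0.96 ± 0.15 on the log2 scale (SE; limma adjusted p = 0.000747), while the difference at 4 h, -0.42 ± 0.15, missed the threshold (adjusted p = 0.0941, but 0.0346 in a fit of the 4 h columns alone). It also fell between 4 h and 20 h, by 0.63 in resting cells (adjusted p = 0.00951, but 0.0854 without donor 2) and by 1.16 with IL-3 (adjusted p = 0.000368). The IL-3 effects on IL6R at both times did not differ past the threshold (interaction -0.54, adjusted p = 0.107). IL6 (chromosome 7, 22727200 to 22731998) was listed at 0 in every column. IL6ST (chromosome 5, 55935095 to 55994963) had at most 0.249 ± 0.19 RPKM in any culture, below the filter, and was not tested. ADAM10 (chromosome 15, 58588809 to 58749707) and ADAM17 (chromosome 2, 9488486 to 9555830), proteases that can release IL6R from the cell surface, had 8.05 ± 1.53 and 4.00 ± 1.12 RPKM in resting cells at 4 h, and neither was called for IL-3 at either time. ADAM17 rose slightly from 4 h to 20 h in resting cells (0.42, adjusted p = 0.0452), a call that leaving out donor 1, 2 or 3 ended (adjusted p 0.218, 0.271 and 0.0683). The change was 0.14 with median-ratio scaling (adjusted p = 0.487) and 0.03 with quantile normalization (0.892), and the call was also lost without the donor block (0.308) and in a fit of the resting columns alone (0.134).

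Among 20 measured genes of IL-6 family signalling, 1 rose, 3 fell and 16 were not called with IL-3 at 4 h (camera adjusted p = 0.832). SOCS1, an inhibitor of cytokine receptor signalling, rose from 8.53 ± 4.80 to 394 ± 97.3 RPKM, and JAK1, a kinase of the receptor complex, fell from 101 ± 4.95 to 76.5 ± 15.1 RPKM (adjusted p = 0.02, but 0.19 without donor 1 and 0.13 without donor 3). At 20 h, 5 rose, 6 fell and 9 were not called (adjusted p = 0.499), with a negative median of -0.27 beside a positive mean of 0.25. Median-ratio scaling turned that median to 0.03. OSM, a cytokine of the IL-6 family, stood at 83.3 ± 9.33 RPKM with IL-3 against 7.87 ± 1.09 in resting cells at 20 h (log2 fold change 3.33 ± 0.22, adjusted p = 4.51e-06). CEBPB, a transcription factor of the IL-6 response, rose from 106 ± 7.10 to 198 ± 27.9 RPKM. Counts adjusted over the list alone were 2 and 3 at 4 h and 5 and 6 at 20 h.

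**Figure D2:**
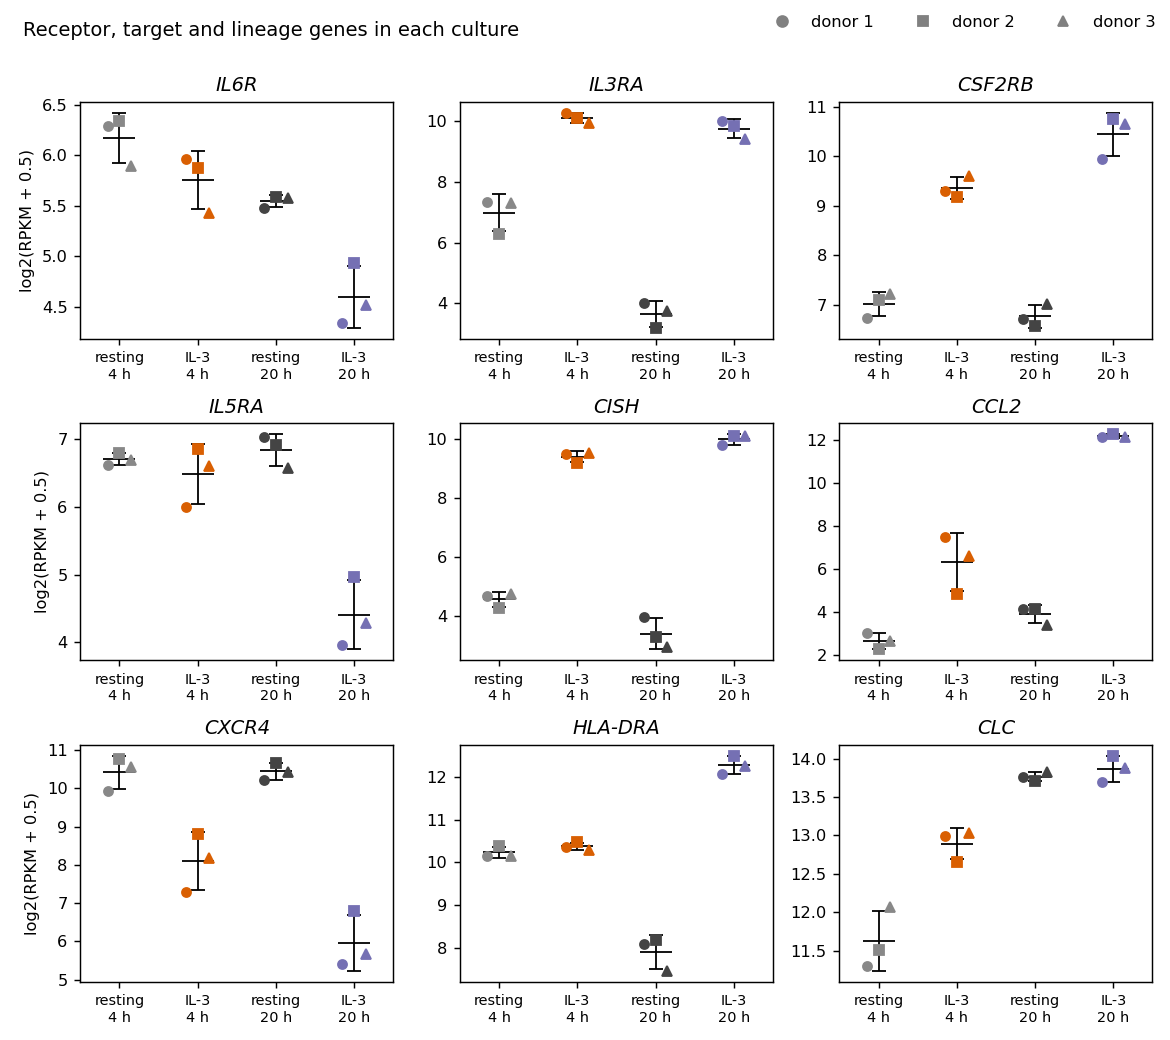
Levels of 9 genes as log2(RPKM + 0.5) (y axis) in the 4 cultures (x axis), with a symbol per donor and bars for the mean and SD of 3 donors. IL3RA and CSF2RB are higher with IL-3 at both times, whereas IL5RA and HLA-DRA separate at 20 h.

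The comparison at 4 h asked what IL-3 changed after a short culture. CISH, a STAT5 target, rose from 23.2 ± 3.88 to 673 ± 85.6 RPKM (log2 fold change 4.84 ± 0.23, limma adjusted p = 4.98e-06, all 3 donors), and SOCS1 and SOCS2, inhibitors of cytokine signalling, each by 5.54 on the log2 scale. IL2RA, the IL-2 receptor alpha chain, went from 7.92 ± 4.62 to 330 ± 92.5 RPKM. FFAR3, a receptor for short-chain fatty acids, went from 11.3 ± 6.19 to 373 ± 120 RPKM. CXCR4, the receptor of the chemokine CXCL12, fell from 1400 ± 393 to 298 ± 147 RPKM (-2.32 ± 0.20, adjusted p = 0.000105).

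In all, 2132 of 12383 genes were called at 4 h, 1106 higher and 1026 lower with IL-3, and 702 of them changed at least 2-fold. The largest rises also held SLC45A3 (0.427 ± 0.0857 to 25.3 ± 7.47 RPKM), FCGR2B, an inhibitory Fc receptor (18.5 ± 11.5 to 383 ± 297), DUSP6, a phosphatase of ERK (16.2 ± 11.3 to 262 ± 118), and the membrane proteins TMEM176B (6.98 ± 5.99 to 90.9 ± 65.1) and TMEM176A (4.52 ± 3.72 to 63.2 ± 46.6). The largest falls were KLHDC8B (95.6 ± 11.4 to 11.2 ± 8.06 RPKM), NRARP, a target of Notch signalling (23.4 ± 20.1 to 2.02 ± 2.15), THBS1, which encodes thrombospondin (293 ± 251 to 62.5 ± 64.8), FOS (324 ± 124 to 60.7 ± 18) and AJAP1 (17.1 ± 9.05 to 3.81 ± 3.32). SLCO4A1, AVP, NR4A2 and NR4A1 followed, with log2 fold changes from -2.13 to -2.02. The tRNA row TRK-TTT3-1 was listed at 0 in resting cells and at 8.21 ± 5.22 RPKM with IL-3, and the microRNA rows MIR6780B and MIR6872 were listed at 0 with IL-3. MIR186 and MIR425 were also among the called falls. Whether reads on such rows came from the small RNA or from a longer transcript was not tested. Leaving out donor 1, 2 or 3 ended the calls of MIR6872 (adjusted p 0.197, 0.0594 and 0.0743) and MIR186 (0.0694, 0.121 and 0.188), and leaving out donor 1 or 3 that of MIR425 (0.21 and 0.175). TRGC1 of the T cell receptor gamma locus, which the rule for naming genes had excluded and which was chosen after its values were seen, went further, from 1.20 ± 1.00 to 176 ± 101 RPKM (6.80 ± 0.51, adjusted p = 4.66e-05).

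Of 22 measured genes of beta common cytokine receptors and STAT5 targets, 15 rose, 2 fell and 5 were not called at 4 h (camera adjusted p = 5.76e-12; adjusted p = 0.0182 with an estimated correlation). IL3RA (chromosome X, 1336785 to 1382689), the IL-3 receptor alpha chain, rose from 133 ± 48.0 to 1110 ± 128 RPKM (3.14 ± 0.23, adjusted p = 4.33e-05). CSF2RB (chromosome 22, 36913628 to 36940439), the beta common chain, rose from 130 ± 22.0 to 661 ± 103 RPKM (2.34 ± 0.16, adjusted p = 2.72e-05), and PIM1, a survival kinase, from 70.2 ± 17.6 to 675 ± 148. IL5RA (chromosome 3, 3066324 to 3110374), the IL-5 receptor alpha chain, had 104 ± 6.27 RPKM without and 91.8 ± 26.4 with IL-3 and was not called (adjusted p = 0.519). Of 14 anti-apoptotic genes 8 rose, none fell and 6 were not called (adjusted p = 4.57e-06; adjusted p = 0.0325 with an estimated correlation), among them BCL2L1 (5.48 ± 1.28 to 22.2 ± 1.93 RPKM) and CFLAR (16.0 ± 1.93 to 29.1 ± 5.01). Among 24 pro-apoptotic genes 4 rose, 2 fell and 18 were not called (adjusted p = 0.832, direction up against a median of -0.04), with CASP9 going from 25.7 ± 4.90 to 54.5 ± 11.7 RPKM. The counts adjusted over the list alone were 15 and 2, 8 and 0, and 5 and 3 for these lists.

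Cytokine genes shifted up at 4 h: of 28 measured, 8 rose, 3 fell and 17 were not called (camera adjusted p = 0.00808). That call was lost with an estimated correlation (adjusted p = 0.109) and without donor 1 (adjusted p = 0.0512). LTB, a membrane-anchored lymphotoxin, rose from 224 ± 28.9 to 1430 ± 136 RPKM, and CCL2, a monocyte chemoattractant, from 5.93 ± 1.67 to 103 ± 76.4. Of 38 activation and adhesion proteins 10 rose, 7 fell and 21 were not called (adjusted p = 0.432), with SELPLG, a selectin ligand, rising from 550 ± 51.0 to 1350 ± 114 RPKM and SEMA7A from 25.3 ± 6.71 to 76.8 ± 26.8. Of 28 ribosome biogenesis and translation genes 8 rose and 1 fell, while 19 were not called (adjusted p = 0.000168). The list lost its call with an estimated correlation (adjusted p = 0.827) and without donor 1 (adjusted p = 0.0626, with 1 rise and 1 fall). The gene that fell was EIF4EBP1, an inhibitor of translation, from 186 ± 32.0 to 92.7 ± 18.6 RPKM. Adjusted over the list alone, 12 rose and 3 fell in the cytokine list, 12 and 10 in the activation list and 14 and 1 in the ribosome biogenesis list.

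Several 4 h lists held changes in both directions. Of 19 immediate early genes 6 rose, 7 fell and 6 were not called (camera adjusted p = 0.889), with KLF2 rising from 33.2 ± 14.5 to 239 ± 75.8 RPKM and NR4A2 falling from 37.4 ± 16.4 to 8.79 ± 3.87. Of 22 eosinophil granule and lineage genes 5 rose, 6 fell and 11 were not called (adjusted p = 0.832). CLC rose from 3240 ± 920 to 7650 ± 1030 RPKM (1.27 ± 0.15, adjusted p = 0.000581), HRH4, a histamine receptor, from 17.3 ± 2.47 to 105 ± 21.8, and the nucleoside transporter SLC29A1 from 649 ± 129 to 1430 ± 301. Of 19 eicosanoid genes 4 rose, 5 fell and 10 were not called (adjusted p = 0.75), with ALOX5, the 5-lipoxygenase, rising from 192 ± 13.5 to 425 ± 51.8 RPKM and PTGER4, a prostaglandin E2 receptor, falling from 56.9 ± 8.4 to 26.2 ± 5.37. In the NF-kappaB feedback list 4 rose and 4 fell of 20 (adjusted p = 0.832). Glycolysis had 6 rises and 2 falls in 22 genes (adjusted p = 0.832), with ENO1 at 217 ± 15.3 and 637 ± 264 RPKM. In the MHC class II list CIITA, the class II transactivator, rose from 4.51 ± 0.62 to 40.1 ± 3.46 RPKM and IFI30, a lysosomal reductase, also rose, while 9 of 11 were not called (adjusted p = 0.432). Of 17 neutrophil markers S100A8 and S100A9 rose, to 5980 ± 1610 and 4790 ± 1100 RPKM, and 15 were not called (adjusted p = 0.832). None of 14 T cell markers, 7 B cell markers and 13 mitochondrially encoded genes was called by limma at 4 h.

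Leaving out donor 1, 2 or 3 at 4 h gave 908, 1057 and 817 called genes. The call of NRARP was lost without donor 2 (adjusted p = 0.11) or donor 3 (0.0623), that of AVP without donor 1 (0.0546) or donor 3 (0.0535), and that of IFI30 without donor 2 (0.0507).

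The comparison at 20 h asked what IL-3 changed after the longer culture. CCL2 rose from 14.9 ± 4.06 to 4730 ± 256 RPKM (log2 fold change 8.30 ± 0.46, limma adjusted p = 1.7e-06, all 3 donors). The calcium-binding proteins S100A8 and S100A9 reached 34200 ± 5140 and 24500 ± 3090 RPKM, from 2190 ± 810 and 1700 ± 473. HLA-DRA of MHC class II went from 246 ± 61.2 to 5000 ± 743 RPKM (4.36 ± 0.13, adjusted p = 1.03e-07). CXCR4 fell from 1400 ± 214 to 67.3 ± 36.7 RPKM (-4.49 ± 0.20, adjusted p = 4.78e-07), and CCR3 from 1750 ± 274 to 355 ± 71.8 (-2.31 ± 0.07).

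In all, 6627 of 12383 genes were called at 20 h, 1713 higher and 4914 lower with IL-3 (25.8% rises), and 2690 changed at least 2-fold. The median over all genes was -0.337. The resting 20 h columns stood apart, with median-ratio scaling factors of 1.178 to 1.209 against 0.929 to 0.981 in all other columns. With median-ratio scaling rises were 50.3% of calls and the median was -0.05, and with quantile normalization 43.9% and -0.078, so the direction of small changes is relative to the scaling. The largest rises included GGT5, an enzyme of glutathione and leukotriene metabolism, which was listed at 0 in resting cells and had 381 ± 51.6 RPKM with IL-3. TMEM176B rose from 4.01 ± 3.20 to 786 ± 380 RPKM, TMEM176A from 3.47 ± 2.23 to 492 ± 191, STAC from 0.0863 ± 0.0747 to 111 ± 32.5, LGALS1, a galectin, from 22.0 ± 5.96 to 2170 ± 528, ROPN1L from 3.84 ± 1.17 to 379 ± 71.9, SOCS2 from 0.184 ± 0.16 to 68.1 ± 5.10 and the chemokine CCL3 from 0.616 ± 1.07 to 78.2 ± 42.2. The largest falls were ACCS (179 ± 74.7 to 8.47 ± 7.79 RPKM), THBS1 (185 ± 111 to 7.74 ± 5.37), C1orf186 (12.8 ± 7.32 to 0.391 ± 0.513) and RGS1, a regulator of G protein signalling (130 ± 32.1 to 9.15 ± 4.78). IFIT2, GNG7, KLHDC8B, PTGER4 and TRANK1 followed, with log2 fold changes from -3.47 to -3.16. The microRNA rows MIR5090, MIR6719, MIR4766, MIR6802 and MIR4746 were also called lower. Leaving out donor 1 ended the calls of MIR5090, MIR4766, MIR6802 and MIR4746 (adjusted p 0.0693, 0.0795, 0.0756 and 0.119). MIR5090 was also lost without donor 2 (0.0669), and MIR6802 and MIR4746 without donor 3 (0.18 and 0.069).

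**Figure D3:**
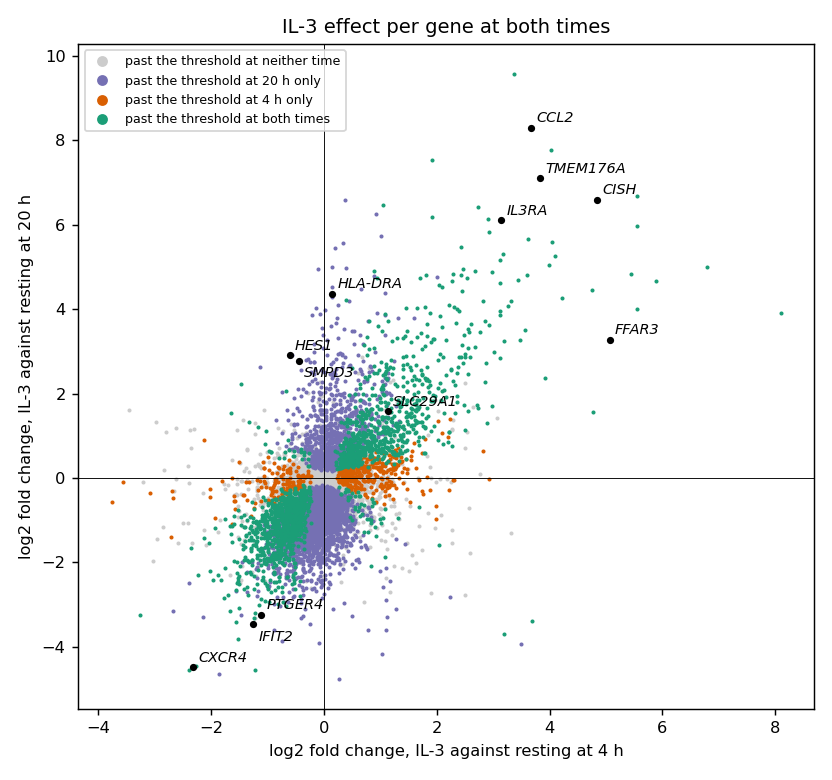
Log2 fold change with IL-3 at 20 h (y axis) against that at 4 h (x axis) for the 12383 tested genes, coloured by whether they passed the threshold at neither, either or both times. CCL2, CISH and IL3RA are higher at both times, CXCR4 is lower at both, and HLA-DRA separates at 20 h.

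Of 22 beta common receptor and STAT5 target genes 17 rose, 3 fell and 2 were not called at 20 h (camera adjusted p = 5.04e-13; adjusted p = 0.0145 with an estimated correlation). IL3RA rose from 12.4 ± 3.5 to 877 ± 174 RPKM (6.11 ± 0.23, adjusted p = 2e-07), CSF2RB from 109 ± 18.2 to 1440 ± 395 (3.68 ± 0.16, adjusted p = 4.37e-07), CISH (chromosome 3, 50606489 to 50611774) from 10.4 ± 4.12 to 1010 ± 119 (6.59 ± 0.23) and CCND3, a D-type cyclin, from 221 ± 37.7 to 2250 ± 107. IL5RA fell from 115 ± 18 to 21.6 ± 8.10 RPKM (-2.44 ± 0.21, adjusted p = 1.85e-05). Of 11 MHC class II genes 10 rose and 1 fell (adjusted p = 6.79e-11; adjusted p = 0.0791 with an estimated correlation). HLA-DPA1 rose from 21.1 ± 12.8 to 599 ± 196 RPKM, HLA-DMB from 9.74 ± 4.58 to 96.0 ± 30.1 and IFI30 from 1130 ± 132 to 6860 ± 130. Beside these, monocyte markers were split: LYZ rose from 65.9 ± 27.8 to 317 ± 178 RPKM and CLEC7A from 0.619 ± 0.291 to 2.86 ± 0.532, a call lost without donor 1 (adjusted p = 0.0853), while 7 of 9 were not called (list adjusted p = 0.221). Without donor 2 the monocyte list was called higher (median 0.92, adjusted p = 0.0122). CD14 had 4.44 ± 6.86 RPKM without and 2.23 ± 2.80 with IL-3. Of 7 B cell markers 1 rose and 1 fell (adjusted p = 0.353). The counts adjusted over the list alone were 17 and 3 for the receptor list and 10 and 1 for class II.

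Of 28 cytokine genes 13 rose, 6 fell and 9 were not called at 20 h (camera adjusted p = 1.96e-05, and 0.0294 with an estimated correlation), among them LTB (176 ± 27.5 to 1510 ± 104 RPKM), CCL23 (7.75 ± 1.61 to 249 ± 62.8) and OSM. The level of OSM with IL-3 at 20 h was above that in resting cells at 20 h but below that in resting cells at 4 h. Of 38 activation and adhesion proteins 18 rose, 13 fell and 7 were not called (adjusted p = 0.000758; adjusted p = 0.0791 with an estimated correlation). ITGAM, an integrin chain, rose from 18 ± 3.53 to 487 ± 13.4 RPKM and CD69, an activation marker, from 12.7 ± 7.66 to 864 ± 125. Of 14 anti-apoptotic genes 9 rose, 2 fell and 3 were not called (adjusted p = 1.59e-05; adjusted p = 0.0299 with an estimated correlation), with BCL2 going from 0.0706 ± 0.122 to 8.77 ± 1.22 RPKM. Of 24 pro-apoptotic genes 5 rose, 9 fell and 10 were not called (adjusted p = 0.569, direction up against a median of -0.39), but with median-ratio scaling 8 rose and 5 fell. Examples are BNIP3L falling from 128 ± 27.9 to 23.7 ± 6.96 RPKM and CASP10 rising from 1.18 ± 0.263 to 9.84 ± 0.882. Of 22 eosinophil lineage genes 8 rose, 6 fell and 8 were not called (adjusted p = 0.146). CAT, which encodes catalase, fell from 621 ± 81.2 to 115 ± 21.7 RPKM, SMPD3, a sphingomyelinase, rose from 9.99 ± 1.51 to 71.1 ± 4.73, and CLC was not called (13900 ± 580 and 15000 ± 1740 RPKM, adjusted p = 0.588), but was called lower with quantile normalization (-0.51, adjusted p = 0.0172). Adjusted over the list alone, rises and falls numbered 13 and 6, 20 and 13, 9 and 2, 5 and 9, and 8 and 6 in these lists.

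Metabolic lists moved at 20 h, and their camera calls were lost with an estimated correlation. Of 23 cholesterol genes 10 rose and 3 fell (adjusted p = 0.000518; adjusted p = 0.443 with an estimated correlation), with EBP, a sterol isomerase, rising from 64.0 ± 3.05 to 382 ± 51.1 RPKM. Of 22 glycolysis genes 7 rose and 4 fell (adjusted p = 0.00271; adjusted p = 0.297 with an estimated correlation), but 13 and 2 with median-ratio scaling, with HK3, a hexokinase, going from 91.9 ± 29.2 to 905 ± 52.3 RPKM. All 13 mitochondrially encoded genes fell (adjusted p = 0.000889; adjusted p = 0.443 with an estimated correlation), but 6 with median-ratio scaling. An example is the cytochrome c oxidase subunit COX2 of the mitochondrial genome, which fell from 3250 ± 280 to 2090 ± 93.1 RPKM. Of 30 nuclear oxidative phosphorylation genes 11 rose and 6 fell (adjusted p = 0.00391; adjusted p = 0.397 with an estimated correlation), but 19 and 0 with median-ratio scaling (adjusted p = 5.99e-06). Of 19 immediate early genes 8 rose and 5 fell (adjusted p = 0.00278; adjusted p = 0.443 with an estimated correlation), with FOSL1 going from 0.233 ± 0.111 to 32.3 ± 6.51 RPKM. Ribosome biogenesis (8 rises, 2 falls, adjusted p = 0.00291) and ER stress genes (7 rises, 6 falls, adjusted p = 0.015) had adjusted p = 0.443 with an estimated correlation. With median-ratio scaling 13 ER stress genes rose and 4 fell. The ER stress call was lost without donor 1 (adjusted p = 0.111), and that of oxidative phosphorylation with quantile normalization (adjusted p = 0.389).

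Other lists were not called by camera at 20 h with the deposited scaling. Of 28 interferon-stimulated genes 4 rose and 16 fell (adjusted p = 0.221), with IFIT2 falling from 42.7 ± 18.2 to 3.99 ± 3.42 RPKM, OASL from 116 ± 22.2 to 23.9 ± 7.70 and IRF9 rising from 70.0 ± 4.15 to 176 ± 13.8. Of 77 ribosomal proteins 8 rose and 35 fell (adjusted p = 0.353), but 17 rose and 14 fell with median-ratio scaling, and the list was called lower with quantile normalization (adjusted p = 0.00842). Eicosanoid genes had 5 rises and 7 falls of 19 (adjusted p = 0.571), but 7 and 4 with median-ratio scaling, with PTGER4 going from 63.3 ± 6.84 to 6.51 ± 2.35 RPKM and TBXAS1, the thromboxane synthase, from 143 ± 21.0 to 397 ± 39.5. Proteases had 6 and 5 of 18 (adjusted p = 0.255), NF-kappaB feedback 6 and 8 of 20 (0.4, but 8 and 6 with median-ratio scaling), glucocorticoid-responsive genes 2 and 4 of 11 (0.824) and cell cycle genes 0 and 7 of 12 (0.063, but 0.0125 with median-ratio scaling). Among 17 neutrophil markers 4 rose and 6 fell (adjusted p = 0.353; 5 and 4 with median-ratio scaling): beside the rise of S100A8 and S100A9, MGAM fell from 5.98 ± 2.08 to 0.321 ± 0.248 RPKM and CSF3R from 23.1 ± 19.9 to 8.75 ± 9.60. T cell markers had 0 rises and 7 falls of 14 (adjusted p = 0.353; 2 falls with median-ratio scaling), NK cell markers 2 and 1 of 6 (0.499), basophil and mast cell markers 2 and 2 of 8 (0.221), platelet markers 2 and 2 of 6 (0.221) and erythroid markers none of 3 (0.815). By fry, which does not compare a list with other genes, the interferon-stimulated (adjusted p = 0.000131), cell cycle (0.000131), glucocorticoid (0.00103), T cell (0.00166), pro-apoptotic (0.00874), ribosomal protein (0.0261), eicosanoid (0.034) and NF-kappaB (0.0378) lists moved down, and the basophil and mast cell (0.0024) and platelet (0.00256) lists up. Fry was run with the deposited scaling only, where the median over all genes was -0.337. The last 4 lists that moved down had medians of -0.39, -0.25, -0.28 and -0.15, so their falls cannot be told from that general shift. The basophil and mast cell list holds IL3RA (log2 fold change 6.11), and fry was not run without this gene. The median was negative and the direction of the camera test was up for pro-apoptotic, eicosanoid, protease, NF-kappaB, neutrophil, NK cell, monocyte and platelet lists. With median-ratio scaling the medians of eicosanoid, protease, NF-kappaB, neutrophil and monocyte lists turned positive (0.02, 0.08, 0.13, 0.04 and 0.03).

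Leaving out donor 2 at 20 h gave 4390 called genes, against 5000 without donor 1 and 4989 without donor 3. Between both times, 742 genes rose with IL-3 at 4 h and at 20 h, where 153 would be shared by chance, and 856 fell at both, against 407.2. The observed counts were 399 to 447 and 255 to 346 without 1 donor, and 435 and 334 without the donor block.

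The comparison of 20 h with 4 h in resting cells described culture without IL-3. The Notch target HES4 fell from 229 ± 53.8 to 1.11 ± 0.91 RPKM (log2 fold change -7.33 ± 0.32, limma adjusted p = 2.53e-06) and HES1, a repressor of the same family, from 68.5 ± 22.7 to 0.663 ± 0.442 (-5.91 ± 0.13, adjusted p = 2.59e-08). CLC rose from 3240 ± 920 to 13900 ± 580 RPKM (2.14 ± 0.15, adjusted p = 2.35e-05). IL3RA fell from 133 ± 48.0 to 12.4 ± 3.5 RPKM (-3.33 ± 0.23, adjusted p = 2.18e-05), whereas CSF2RB and IL5RA were not called (adjusted p = 0.221 and 0.62). CSF2RB was called lower with median-ratio scaling (-0.56, adjusted p = 0.0261). CISH fell by 1.17 ± 0.23 (adjusted p = 0.00291).

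In all, 5602 genes were called, 4296 higher and 1306 lower at 20 h (76.7% rises), and the median over all genes was 0.28. Rises were 45.6% of calls with median-ratio scaling and 54.0% with quantile normalization, with medians of 0.003 and 0.044. Other large falls were PI3, an elastase inhibitor, with means of 97.9 ± 153 and 0.728 ± 1.26 RPKM, SPAG4 (22.9 ± 2.21 to 0.369 ± 0.198), HIC1 (15.9 ± 11.5 to 0.11 ± 0.0966) and the microRNA row MIR23A. The largest rises held C1orf186 (0.501 ± 0.443 to 12.8 ± 7.32 RPKM) and 4 microRNA rows listed at 0 in resting cells at 4 h, MIR939, MIR628, MIR601 and MIR4673. The call of MIR628 was lost without donor 1 (adjusted p = 0.0634) or donor 3 (0.0623). SPP1, which encodes osteopontin (1.20 ± 0.232 to 18.2 ± 7.11 RPKM), NIPSNAP1 (1.85 ± 0.836 to 19.8 ± 2.58), BICDL2 and RAB3C followed.

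Of 28 interferon-stimulated genes 1 rose, 21 fell and 6 were not called in resting cells (camera adjusted p = 2.93e-17; adjusted p = 0.00667 with an estimated correlation), with IFI6 falling from 138 ± 34.1 to 9.08 ± 2.43 RPKM and TRIM22 from 20.9 ± 4.92 to 2.36 ± 0.51. NF-kappaB feedback genes fell, 11 of 20 against 1 rise (adjusted p = 5.51e-08; adjusted p = 0.00938 with an estimated correlation), such as BCL3 from 409 ± 124 to 110 ± 36.3 RPKM. Of 38 activation and adhesion proteins 19 fell and 2 rose (adjusted p = 1.41e-09; adjusted p = 0.00938 with an estimated correlation), with TNFRSF1B, a TNF receptor, going from 492 ± 123 to 148 ± 9.77 RPKM. Of 28 cytokine genes 11 fell and 1 rose (adjusted p = 1.21e-05; adjusted p = 0.0144 with an estimated correlation), with OSM falling from 160 ± 64.9 to 7.87 ± 1.09 RPKM, CXCL16 from 227 ± 50.1 to 19.0 ± 9 and AREG, an EGF receptor ligand, from 256 ± 181 to 31.5 ± 19.1. Of 22 beta common receptor genes and STAT5 targets 8 fell and 1 rose (adjusted p = 5.78e-05; adjusted p = 0.0495 with an estimated correlation). Of 11 class II genes 8 fell and none rose (adjusted p = 4.37e-09; adjusted p = 0.0717 with an estimated correlation): HLA-DRA fell from 1210 ± 114 to 246 ± 61.2 RPKM and CD74, the invariant chain, from 4580 ± 1020 to 1210 ± 237. Of 19 immediate early genes 14 fell and 2 rose (adjusted p = 4.37e-09; adjusted p = 0.0832 with an estimated correlation), with DUSP1 going from 352 ± 67.7 to 127 ± 21.0 RPKM and KLF6 from 325 ± 54.6 to 591 ± 73.7. Falls adjusted over the list alone were 23, 12, 20, 11, 8, 8 and 14 in the order given. Markers of other blood cells were also called lower as lists: neutrophil (5 falls of 17, adjusted p = 0.00336; adjusted p = 0.271 with an estimated correlation), monocyte (1 of 9, 0.0122; 0.0822 with an estimated correlation) and NK cell markers (3 of 6, 0.045; 0.155 with an estimated correlation). Median-ratio scaling ended the monocyte (0.0814) and NK cell (0.197) calls. The NK cell call was also lost without donor 2 (0.294, no falls) or donor 3 (0.0606), without the donor block (0.19), with quantile normalization (0.0801) and with a pseudocount of 1 (0.052).

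Eosinophil lineage genes had 4 rises and 9 falls of 22 in resting cells (camera adjusted p = 0.00371; adjusted p = 0.163 with an estimated correlation and 0.173 with quantile normalization), but 1 and 11 with median-ratio scaling. CAT fell from 1350 ± 238 to 621 ± 81.2 RPKM and SIGLEC10, an inhibitory lectin, from 646 ± 202 to 347 ± 85.7. Of 19 eicosanoid genes 7 rose and 2 fell (adjusted p = 0.966), but 5 and 6 with median-ratio scaling, with HPGD, a prostaglandin dehydrogenase, rising from 20.8 ± 16.6 to 135 ± 107 RPKM and CYSLTR2, a leukotriene receptor, falling from 24.4 ± 7.60 to 3.93 ± 2.12. Of 30 oxidative phosphorylation genes 17 rose and none fell (adjusted p = 0.0645), but with median-ratio scaling 2 rose and 7 fell, and with quantile normalization 16 rose and 1 fell (adjusted p = 0.000424). Leaving out donor 2 or 3 gave 3241 and 3470 called genes.

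The comparison of 20 h with 4 h in the presence of IL-3 described the course of the IL-3 culture. CCL2 rose from 103 ± 76.4 to 4730 ± 256 RPKM (log2 fold change 5.88 ± 0.46, limma adjusted p = 2.35e-05) and HLA-DRA from 1330 ± 81.5 to 5000 ± 743 (1.90 ± 0.13, adjusted p = 1.29e-05). HES4 fell from 137 ± 37.0 to 0.985 ± 1.06 RPKM (-6.72 ± 0.32) and IFI6 from 132 ± 27.6 to 3.51 ± 2.35 (-5.17 ± 0.19). CSF2RB rose by 1.09 ± 0.16 (adjusted p = 0.000607) and CLC by 0.98 ± 0.15 (0.000874), and IL5RA fell by 2.08 ± 0.21 (7.77e-05). IL3RA and CISH were not called (adjusted p = 0.248 and 0.0665), and CISH passed the threshold without donor 1 (adjusted p = 0.0329).

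In all, 4840 genes were called, 2379 higher and 2461 lower at 20 h. Large rises were STAC (2.22 ± 1.99 to 111 ± 32.5 RPKM), GGT5 (15.8 ± 9.95 to 381 ± 51.6), APOL4 (0.581 ± 0.456 to 26.8 ± 7.68), CLU, which encodes clusterin (1.70 ± 0.557 to 35.3 ± 14.2), and the microRNA row MIR1182, listed at 0 with IL-3 at 4 h. Large falls were SPAG4 (19.4 ± 7.17 to 0.15 ± 0.182 RPKM), PDE4B, a phosphodiesterase that breaks down cyclic AMP (119 ± 46.6 to 5.15 ± 2.49), and PI3 (93.8 ± 150 and 1.15 ± 1.73). Of 28 interferon-stimulated genes 22 fell and 1 rose (camera adjusted p = 1.79e-11; adjusted p = 0.0204 with an estimated correlation), with MX2 going from 19.4 ± 9.30 to 1.81 ± 1.54 RPKM and XAF1 from 9.22 ± 1.74 to 0.708 ± 0.407. Of 20 NF-kappaB feedback genes 15 fell and 1 rose (adjusted p = 0.000235; adjusted p = 0.0492 with an estimated correlation), such as RELB from 29.1 ± 10.1 to 8.43 ± 1.54 RPKM. Of 11 class II genes 9 rose and 1 fell (adjusted p = 0.00138; adjusted p = 0.588 with an estimated correlation), with HLA-DPB1 going from 66.5 ± 36.2 to 448 ± 161 RPKM. Of 23 cholesterol genes 13 rose and 1 fell (adjusted p = 0.00204; adjusted p = 0.631 with an estimated correlation, and 0.0853 without donor 1), with SQLE, squalene epoxidase, at 0.597 ± 0.281 and 8.78 ± 8.10 RPKM. Of 30 oxidative phosphorylation genes 18 rose and 1 fell (adjusted p = 0.000314; adjusted p = 0.301 with an estimated correlation), with NDUFB3 rising from 265 ± 12.2 to 563 ± 33.4 RPKM. Adjusted over the list alone there were 24 and 16 falls in the first pair of lists and 9, 15 and 19 rises in the others.

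Further lists had changes in both directions with IL-3 from 4 h to 20 h. Cytokines had 7 rises and 11 falls of 28 (camera adjusted p = 0.626), with CSF1 falling from 93.8 ± 8.27 to 25.7 ± 3.15 RPKM and IL18 rising from 9.27 ± 3.32 to 28.7 ± 7.64. Activation and adhesion proteins had 8 and 17 of 38 (adjusted p = 0.214), eosinophil lineage genes 6 and 9 of 22 (0.426) and glycolysis 10 and 2 of 22 (0.0654), with GAPDH rising from 777 ± 259 to 1650 ± 263 RPKM. Among neutrophil markers 3 rose and 6 fell of 17 (adjusted p = 0.426), S100A8 and S100A9 being among the rises. Genes that changed with time overlapped between the cultures: 1608 rose in both, against 825.3 by chance, and 859 fell in both, against 259.6. These counts were not refitted under the alternatives. Leaving out donor 2 or 3 gave 2837 and 3074 called genes.

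**Figure D4:**
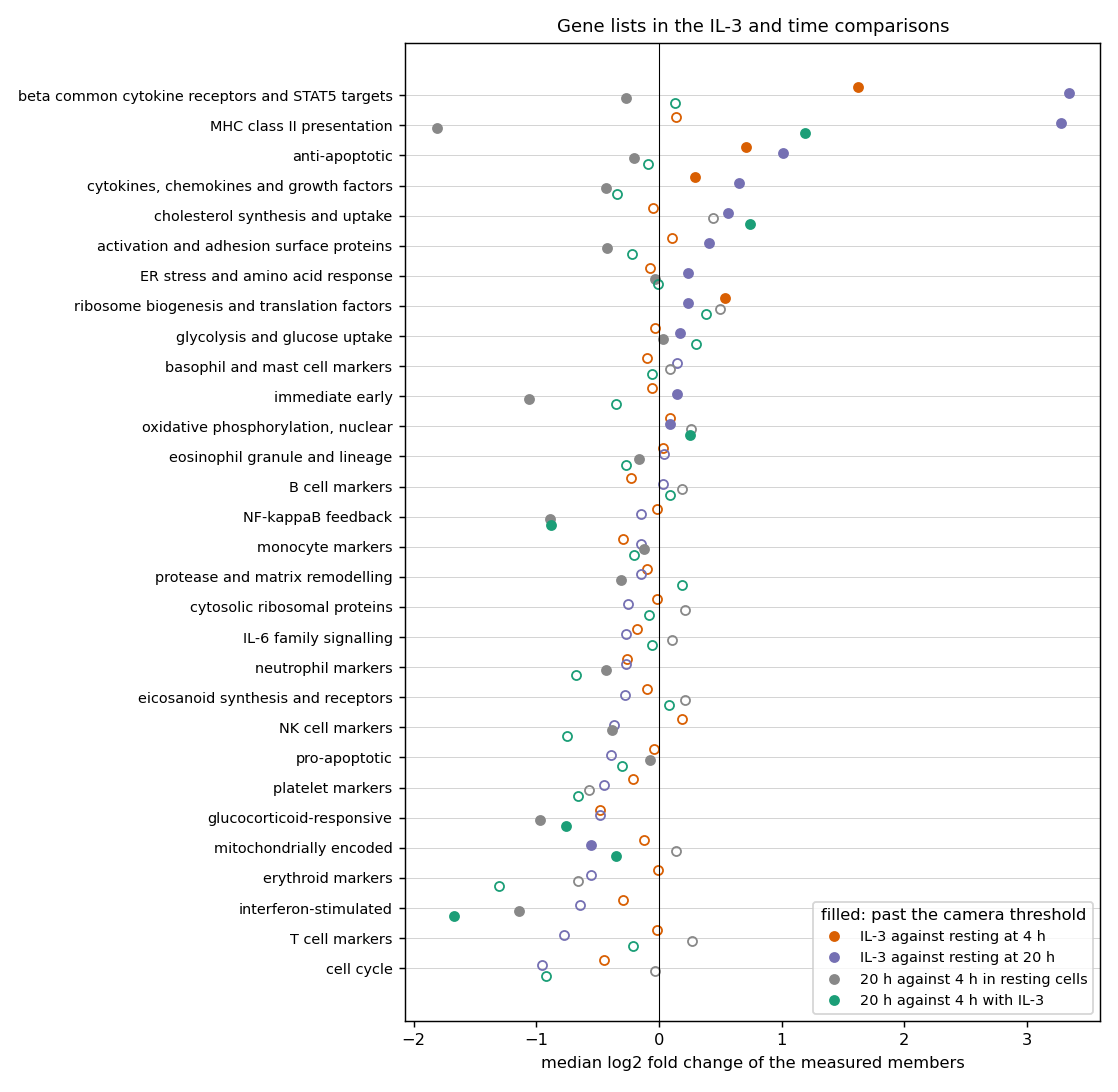
Median log2 fold change of the measured members of each of 30 gene lists (x axis) in the IL-3 and time comparisons, coloured by comparison and filled where camera passed the threshold with the preset correlation. The class II list has medians of 3.28 with IL-3 at 20 h and -1.81 between 4 h and 20 h in resting cells.

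The interaction asked whether the IL-3 effect at 20 h differed from that at 4 h. The IL-3 effect was larger at 20 h for LGALS1, by 6.22 ± 0.43 on the log2 scale (limma adjusted p = 6.27e-05), and for HLA-DRA (4.22 ± 0.19, adjusted p = 9.26e-06). The IL-3 effect on IL3RA was larger at 20 h by 2.97 ± 0.33 (adjusted p = 0.000685), its resting level having fallen between the times. It was lower at 20 h for IL5RA (-2.22 ± 0.29, adjusted p = 0.0015), CAT (-2.01 ± 0.12, adjusted p = 2.34e-05) and CCR3 (-1.77 ± 0.10, adjusted p = 2.78e-05). For CLC it was lower by 1.16 ± 0.21 on the log2 scale, with an interaction of -1.16 (adjusted p = 0.00651, but 0.0606 without donor 1).

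In all, 2611 genes had an interaction past the threshold, 608 positive and 2003 negative (23.3% positive), with a median of -0.298 over all genes. The positive share was 61.9% with median-ratio scaling and 48.7% with quantile normalization, with medians of -0.018 and -0.047. The resting 20 h columns, whose median-ratio scaling factors stood apart, enter this difference. Negative interactions numbered 667 with median-ratio scaling. Large positive interactions were also those of GGT5, listed at 0 in resting cells at 20 h, STAC (5.61 ± 0.54), ROPN1L (5.43 ± 0.39) and LMNA, which encodes lamin A and C (5.33 ± 0.59, 1.16 ± 0.60 to 123 ± 30.0 RPKM at 20 h). Large negative ones were those of C1orf186, RMI2, ACCS and GNG7, from -3.83 to -2.91, and of the microRNA rows MIR6802, MIR4298, MIR4518, MIR4425 and MIR4766, each with a group at or near 0. Leaving out donor 2 ended the calls of RMI2 (adjusted p = 0.0568) and GNG7 (0.0645), and leaving out donor 3 those of MIR6802 (0.164), MIR4298 (0.0959), MIR4425 (0.0524) and MIR4766 (0.214). MIR4298 and MIR4766 were also lost without donor 1 (0.0648 and 0.282), and MIR4425 without donor 2 (0.0834).

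Of 11 class II genes 8 had a positive interaction and none a negative one (camera adjusted p = 2.14e-14; adjusted p = 0.0668 with an estimated correlation). Of 22 beta common receptor and STAT5 target genes 8 were positive and 2 negative (adjusted p = 1.38e-07, and 0.0418 with an estimated correlation), including OSM (3.07 ± 0.32) and CCND3 (1.52 ± 0.18). The resting level of OSM had fallen between the times, and its level with IL-3 at 20 h was below its resting level at 4 h. Of 28 cytokine genes 7 were positive and 2 negative (adjusted p = 8.97e-05; adjusted p = 0.0418 with an estimated correlation), such as CCL23 (4.02 ± 0.32) and CSF1 (-2.13 ± 0.24). Of 38 activation proteins 11 were positive and 9 negative (adjusted p = 0.000494; adjusted p = 0.0863 with an estimated correlation), but 14 and 2 with median-ratio scaling, with ITGAM at 3.80 ± 0.24 and CD69 at 4.26. Immediate early genes had 8 positive and 0 negative of 19 (adjusted p = 1.46e-07; adjusted p = 0.14 with an estimated correlation), with JUND at 1.60 ± 0.25, a call lost without donor 2 (adjusted p = 0.0618). Glycolysis had 6 positive and 2 negative of 22 (adjusted p = 0.000142; adjusted p = 0.14 with an estimated correlation), with HK3 at 2.57 ± 0.23 and SLC2A3 at 1.58 ± 0.24. Eosinophil lineage genes had 3 and 4 of 22 (adjusted p = 0.589), with SMPD3 at 3.22 ± 0.16. Leaving out donor 1, 2 or 3 gave 1104, 415 and 782 genes with an interaction past the threshold, 32.1%, 45.8% and 33.6% of them positive.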

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

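The tests against sequencing depth, IL-3 treatment for 4 h, monocytes and B cells were chosen after the results were seen.

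The IL-3 effect differed between 20 h and 4 h, by the limma test of that difference, for 2611 genes (n = 3 per group). Among 172 named genes 104 passed it, with a largest adjusted p of 0.0485. Positive differences (log2, 20 h minus 4 h) were those of LGALS1 6.22, GGT5 6.19, STAC 5.61, ROPN1L 5.43, LMNA 5.33, HLA-DPB1 5.05, HLA-DPA1 4.84, APOL4 4.73, CCL2 4.62, CLU 4.58, CD69 4.26, HLA-DRA 4.22, CCL23 4.02, ITGAM 3.8, MIR1182 3.77, TMEM176B 3.76, CCL3 3.69, HES1 3.52, TMEM176A 3.27, HLA-DMB 3.22, SMPD3 3.22, MIR6780B 3.18, CD74 3.11, OSM 3.07, FOSL1 3.04, AVP 3.03, IL3RA 2.97, S100A9 2.81, SQLE 2.73, S100A8 2.59, HK3 2.57, BCL2 2.38, IL10RA 2.31, ICAM1 2.2, IFI30 2.1, LYZ 2.04, STARD4 2.03, GAPDH 1.8, CISH 1.76, NR4A1 1.75, PIM2 1.61, JUND 1.6, SLC2A3 1.58, CXCL16 1.53, SLC2A1 1.53, CCND3 1.52, CSF2RB 1.34, IL18 1.24, SREBF2 1.24, IRF9 1.02, TBXAS1 0.87, EBP 0.84, PIM1 0.81, CFLAR 0.79, LDHA 0.69, CEBPB 0.65, IER5 0.6, NDUFB3 0.6, SLC29A1 0.45. Negative ones were those of MIR6802 -7.42, MIR4298 -7.06, MIR4518 -6.89, MIR4425 -5.27, MIR4766 -5.2, MIR628 -5.05, MIR4673 -4.71, C1orf186 -3.83, MIR939 -3.63, RMI2 -3.63, ACCS -3.33, GNG7 -2.91, PDE4B -2.91, MGAM -2.57, RGS1 -2.3, RAB3C -2.27, IL5RA -2.22, IFIT2 -2.21, CXCR4 -2.17, THBS1 -2.15, CSF1 -2.13, PTGER4 -2.12, SPP1 -2.1, BNIP3L -2.06, CAT -2.01, BICDL2 -1.96, FFAR3 -1.79, CCR3 -1.77, NIPSNAP1 -1.72, MX2 -1.65, TRANK1 -1.5, IFI6 -1.31, CASP9 -1.25, TRIM22 -1.2, CSF3R -1.18, CLC -1.16, NFKBIZ -1.13, OASL -1, LTA4H -0.83, RELB -0.77, ALOX5 -0.73, ND1 -0.63, JAK1 -0.52, COX2 -0.5, NDUFS7 -0.35. For genes listed at 0 in a group, GGT5 and microRNA rows among them, the value depends on the pseudocount. Without donor 1, 2 or 3, 69, 60 and 65 of the 104 kept their call (99, 101 and 100 were tested), and 47 kept it in all 3 fits. Median-ratio scaling kept 90, quantile normalization 89 and a fit without the donor block 62, and no sign was reversed. Among the calls lost without 1 donor were those of MIR6802 (adjusted p 0.164, donor 3), MIR4298 (0.0648, donor 1; 0.0959, donor 3), MIR4425 (0.0834, donor 2; 0.0524, donor 3), MIR4766 (0.282, donor 1; 0.214, donor 3), RMI2 (0.0568, donor 2), GNG7 (0.0645, donor 2), CSF2RB (0.0565, donor 3), CISH (0.0834, donor 2), CLC (0.0606, donor 1), JUND (0.0618, donor 2), FOSL1 (0.0787, donor 3) and NR4A1 (0.115, donor 1; 0.0907, donor 3).

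The same difference passed the camera threshold for 14 of 30 lists. The adjusted p was 2.14e-14 for MHC class II, 1.38e-07 for beta common receptors and STAT5 targets, 1.46e-07 for immediate early genes, 8.97e-05 for cytokines, 0.000142 for glycolysis, 0.000193 for cholesterol, 0.000494 for activation proteins and 0.000995 for mitochondrially encoded genes. It was 0.0134 for ER stress, 0.014 for anti-apoptotic genes, 0.0239 for oxidative phosphorylation, 0.0256 for monocyte markers, and 0.032 for proteases and for platelet markers. Relative to all genes, whose median was -0.298, the mitochondrially encoded list was lower and the other 13 were higher, though the medians of anti-apoptotic genes and platelet markers were -0.04 and -0.13. With an estimated correlation 12 of the 14 calls were lost, and the beta common and cytokine lists passed (adjusted p 0.0418 each). The lost ones had 0.0668 for class II, 0.0863 for activation proteins, 0.14 for immediate early, glycolysis, anti-apoptotic, protease and monocyte lists, 0.267 for platelet, 0.324 for oxidative phosphorylation, 0.354 for cholesterol, 0.456 for ER stress and 0.508 for mitochondrially encoded genes. Leaving out donor 1 ended the calls of cholesterol, oxidative phosphorylation, ER stress and platelet lists (0.0612 each), proteases (0.128) and monocyte markers (0.106). Proteases were also lost without donor 3 (0.0753), and platelet markers without donor 2 (0.241) or donor 3 (0.146). Median-ratio scaling ended the calls of mitochondrially encoded genes (0.119), monocyte markers (0.222), platelet markers (0.229) and proteases (0.0968). Quantile normalization ended those of oxidative phosphorylation (0.506), proteases (0.216) and platelet markers (0.116).

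The splits of the columns were too few for a share under 0.05. In 1 of 10 splits, the real one, as many genes were called for each IL-3 and time comparison: 2132 at 4 h, 6627 at 20 h, 5602 with time in resting cells and 4840 with time and IL-3, against at most 3, 1, 3 and 3 in the others. For the difference between times 1 of 4 assignments gave as many, 2611 against 0. Each other split or assignment mixed cultures within a group, so the real difference entered its residual spread. Few calls there were fixed in advance, and the contrast is not support for the calls.

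With IL-3 at 20 h more genes fell than rose (25.8% rises). Leaving out the 100 genes of the largest read share and rescaling gave a median of -0.29 over the others, against -0.32 as deposited, so abundant genes taking reads were not the whole reason. The share of rises fell with exon length, from 36.2% to 27.1% and 18.1% in 3 equal groups of genes, but even the highest stayed below 50%, and it was 31.3% among genes with a mean of at least 10 RPKM, which argues against gene length or background as the whole reason. Median-ratio scaling gave 50.3% rises. Its factors were 1.178 to 1.209 in the resting 20 h columns and 0.929 to 0.981 in all other columns. The median change from 4 h to 20 h was 0.28 in resting cells and -0.009 with IL-3. The general shift therefore lay in the resting 20 h columns, and it is not shown to be a lowering by IL-3. Whether total RNA per cell differed stays open, as nothing in the table measures it.

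The IL-3 4 h column of donor 2 listed 22976 genes above 0. In 8 columns depth was larger and fewer genes were listed, which argues against depth. IL-3 added at most 56 genes in the other donors, against 3751 in donor 2. Olfactory receptor genes, silent in blood, were above 0 for 16.2% of 370, 6 times the median of the other 11 columns (2.7%, highest 17.3%). This describes reads spread over silent genes, but it largely restates the higher count, and another column had a higher share. The test therefore gives no cause, and no biological explanation was tested for that spread.

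MHC class II genes were higher with IL-3 at 20 h. The median of 9 monocyte markers was -0.15, with CD14 at 4.44 ± 6.86 and 2.23 ± 2.8 RPKM, although LYZ rose, and it was 0.92 without donor 2 (camera adjusted p = 0.0122). The median of 7 B cell markers was 0.03, with MS4A1 at 1.63 ± 1.85 and 0.532 ± 0.712 RPKM. Both medians stayed below the class II median of 3.28, which was at least 3.58 under both other scalings. From 4 h to 20 h the class II median was -1.81 in resting cells and 1.19 with IL-3. Part of the difference at 20 h was therefore a fall in resting cells. A candidate explanation for the rise is induction by IL-3 in eosinophils, a hypothesis from the data it was tested on. It does not cover the fall, and only monocytes and B cells were examined as other sources.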

How the results depend on the processing

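Fits without the IL-3 4 h column of donor 2, without the resting 20 h column of donor 1 and without small RNA rows were added after the data were seen. The cause of a change was not tested unless stated.

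Of 271 named gene results past the threshold, 229 stayed past it with the same sign under every alternative counted, and 42 did not under at least 1, none with a reversed sign. Of all 104 named genes with a difference between times, some of them among these results, 47 kept it in every fit without 1 donor. Of 18 results not past the threshold 9 changed, 6 of them in sign. The totals for named gene results left out limma without the trend and any fit in which a gene was not tested. Most of these genes were named for large calls in the main fit, so their share need not hold for all calls. At 4 h, 788 to 982 of all 2132 calls were kept without 1 donor. Of 54 list results past the threshold 14 stayed so. An estimated inter-gene correlation ended 40. Of 96 others 81 stayed below it.

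Called genes at 4 h, 20 h, with time in resting cells, with time and IL-3, and for the difference between times were 2132, 6627, 5602, 4840 and 2611. Requiring a log2 fold change of at least 1 left 702, 2690, 1952, 1733 and 1295, by construction. Without the filter on low values, with 29253 genes tested, the 4 h count was 1389 and the difference count 1505. Quantile normalization gave 1568 for the difference. Without the donor block, so ignoring the pairing, 997 were called at 4 h and 1109 for the difference. Leaving out 1 donor gave 817 to 1057, 4390 to 5000, 3241 to 3907, 2837 to 3742 and 415 to 1104, with fewer columns. Other alternatives stayed within 1.5 times.

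Genes that rose at both times with IL-3 numbered 742 (435 without the donor block, 399 to 447 without 1 donor), and those that fell 856 (334, 255 to 346, and 493 without the filter).

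Some values changed sign. With IL-3 at 4 h ADAM10 (0.02) ranged from -0.18 to 0.3 without 1 donor (-0.05 without donor 1, -0.18 without donor 3), and at 20 h (0.14) from -0.04 (without donor 3) to 0.4. At 20 h ADAM17 (-0.28) was 0.01 with median-ratio scaling and 0.1 with quantile normalization. CLC (0.1) was -0.51 with quantile normalization (adjusted p = 0.0172) and ranged from -0.01 (without donor 2) to 0.19 without 1 donor. With time in resting cells ADAM10 (0.15) was -0.14 with median-ratio scaling and -0.23 with quantile normalization, and IL5RA (0.14) was -0.17 with median-ratio scaling and -0.13 without the resting 20 h column of donor 1.

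Not run, as the table holds 12 columns and no counts, were fits of 24 libraries, a block of library number, each numbered library alone, DESeq2 and edgeR. At these depths RPKM 1 over 2 kb rests on 15.4 to 20.9 reads, and the 19 small RNA rows named rest on 3 to 30.4.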

Other observations

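The genes in this part, other than those of the Notch test, were chosen after their values were seen.

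T cell receptor genes had been excluded by the rule for naming genes, but TRGC1 and TRGC2 of the gamma locus rose with IL-3 at 4 h more than the genes it named. TRGC1 went from 1.20 ± 1.00 to 176 ± 101 RPKM (log2 fold change 6.80 ± 0.51, limma adjusted p = 4.66e-05, 3 of 3 donors) and TRGC2 from 1.46 ± 1.61 to 101 ± 45.2 (5.89, adjusted p = 3.72e-05, 3 of 3). TRGJP1, TRGJP2 and TRGJ2 were listed at 0 in resting cells at 4 h and had 154 ± 92.4, 24.4 ± 10.1 and 13.8 ± 5.09 RPKM with IL-3. The variable gene TRGV9 had 3.15 ± 2.37 and 4.86 ± 3.28 RPKM (adjusted p = 0.457). TRAC had 9.74 ± 15.7 and 7.44 ± 11.7 (0.781), TRBC2 15.7 ± 23.3 and 15.4 ± 24.4 (0.821) and CD3D 8.45 ± 13.0 and 6.24 ± 10.2 (0.294). At 20 h TRGC1 had 0.668 ± 0.924 and 42.7 ± 43.7 RPKM (adjusted p = 4.87e-05).

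With the deposited scaling the IL-3 effect was called at 4 h and at 20 h with opposite signs for 78 genes. Of these, 49 rose at 4 h and fell at 20 h, against 438.9 by chance, and 29 did the reverse, against 141.9. Opposite signs were thus rarer than by chance. HES1 had log2 fold changes with IL-3 of -0.61 and 2.91, SMPD3 -0.44 and 2.78, PDE4B 0.83 and -2.08 and TNFAIP8 1.68 and -0.68. Between 4 h and 20 h HES1 fell in both cultures. It went from 68.5 ± 22.7 to 0.663 ± 0.442 RPKM in resting cells and from 47.7 ± 23.3 to 8.28 ± 3.44 with IL-3. The positive value of HES1 at 20 h was therefore a smaller fall with IL-3, not a rise over time. FFAR3 was higher with IL-3 at both times, at 373 ± 120 RPKM at 4 h and 21.6 ± 5.18 at 20 h.

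HES4, HES1 and NRARP fell in resting cells between 4 h and 20 h, and the hypothesis that Notch target genes fall together was tested on other Notch genes. Of 16 listed 7 were measured, 2 were called lower (NOTCH2 and NOTCH4) and 1 higher (HES6). Both genes called lower were receptors, and NOTCH4 was weakly expressed (1.14 ± 0.0973 to 0.3 ± 0.0296 RPKM). HES6 rose by 0.38, beside a median of 0.28 over all genes. The other measured genes, DTX2, DTX4, LFNG and the receptor NOTCH1, were not called, so no measured gene other than receptors was called lower. The test counted targets and receptors together and left the hypothesis open.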
